A study of Homo sapiens with 9 samples.

How the data were processed

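The series comprised 9 RNA sequencing libraries of KYSE-150, an established human esophageal squamous cell carcinoma line. Per the labels, 3 libraries came from control cells called wild type, 3 from cells overexpressing PAK5 and 3 from cells in which PAK5 was silenced. PAK5 is a serine/threonine kinase of the p21-activated kinase family. The labels name no empty-vector or scrambled control, and the silenced libraries carry both an si and an shRNA name, so the kind of silencing reagent is not stated further. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

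The authors deposited 1 table of FPKM values (fragments scaled to gene length and library size) with 1 column per library and 41235 genes. Per the submitters' processing notes the genome build was GRCh38. The aligner, the quantification tool, the gene annotation and the strand setting are not given in the sources used here. Per the labels' series design, the submitters compared silenced with control cells in DESeq2 at a false discovery rate of 0.05 and an absolute log2 fold change of at least 1. DESeq2 needs counts and was not run here, because the deposited values are FPKM and not counts. Depth is therefore unknown, and no counting interval or detection floor is given. An exact 0 is reported as listed at 0. The FPKM columns summed to between 360975 and 446376, all 9 value columns were used, no 2 libraries were identical, and 0 of 53 ribosomal protein and oxidative phosphorylation genes were listed at 0 in any library.

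FPKM values were analysed as log2(FPKM + 1), so a fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. Genes with a mean FPKM of at least 1 over the 9 libraries were kept, which left 12980 genes, PAK5 among them. Each comparison was a contrast in 1 linear model of all 9 libraries fitted with limma 3.58.1 in R 4.3.3, with moderated variances and a trend on mean expression. Adjusted p-values are Benjamini-Hochberg values over the 12980 genes from limma. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1, the thresholds of the series design. The words rose and fell are used of genes with an adjusted p under 0.05. PAK5 was also compared with a two-sided exact permutation test, which with 3 libraries against 3 cannot go below p = 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

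Before the data were examined, the comparisons, the thresholds, the filter, the alternatives and 32 gene lists were fixed. The lists were the PAK family, G1/S and DNA replication, G2/M and mitosis, apoptosis regulators, p53 targets, mesenchymal genes of the epithelial-mesenchymal transition, epithelial junction genes, squamous basal and lineage genes, squamous differentiation genes, matrix proteases and inhibitors, NF-kB targets and cytokines, interferon response, antigen presentation, integrated stress and unfolded protein response, hypoxia and glycolysis, cholesterol biosynthesis, YAP/TEAD targets, ERK pathway output, immediate early genes, Wnt/beta-catenin targets, TGF-beta targets, NRF2 targets, nuclear-encoded oxidative phosphorylation, cytoplasmic ribosomal proteins, mitochondrially encoded mRNAs, replication-dependent histones, and markers of leukocytes, fibroblasts, endothelium, neurons and glandular epithelium. One further list and some single genes are not reported here. Of 699 list entries, 675 matched a gene of the table. Lists with at least 3 tested members, 30 of the 32, were tested with limma's camera against all other tested genes at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. Member counts are given over all genes tested and with p-values adjusted over the list alone. The tests of lists between the overexpressing and the silenced libraries were added after the data were seen.

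The genes named were fixed by rule: PAK5, then up to 8 called protein-coding genes with the highest rise and up to 8 with the deepest fall against control whose 3 libraries all lay beyond the other 3. To these were added up to 4 members with the smallest adjusted p per list, up to 5 genes per direction between the overexpressing and silenced libraries, and up to 5 per direction among genes that changed in both modified groups. Genes named outside this rule are said to be. Symbols came from a table of gene identifiers that matched 41168 of the 41235 genes, and gene types and positions from GENCODE release 29 on GRCh38, which held 39166 of them. Genes with near-identical copies (ALPP, SAA2, KRT81) and genes that overlap another on the opposite strand are uncertain, since the strand setting and the handling of shared reads are not stated.

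The fit was tested on simulated data with the residual covariance of these libraries, 12980 genes and 200 genes of known change in the silenced libraries, in 10 runs. Of 100 genes changed by a log2 fold of 2 in FPKM itself, 90.9% reached an adjusted p under 0.05 and 86.5% were called. For a log2 fold of 1 the shares were 60% and 18.1%. In these 10 runs false positives had a median of 0 and a maximum of 10 genes. Far higher numbers can occur. Among the 100 simulated sets of unchanged groups described below, up to 1119 genes passed in both comparisons in 1 direction. A separate simulation of silenced against control libraries used the same residual covariance and 12980 genes, without those 200 changes. In it 1 list was shifted by 1 on the log2(FPKM + 1) scale. With 32 lists, 30 of them tested, the shifted list was called in 10 of 10 runs. The preset correlation also called a median of 4 and at most 5 unshifted lists per run. The estimated correlation called the shifted list in 9 of 10 runs and 0 unshifted lists. The largest mean log2 fold change of a called list in the data was 0.76, for ERK output in silenced libraries. The simulation therefore does not show how often the estimated correlation would call shifts of the sizes observed.

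Because both modified groups were compared with the same 3 control libraries, their fold changes share chance values. The overlap of the 2 comparisons was set beside 100 simulated sets of unchanged groups and beside independent lists. Alternatives covered the pseudocount, the filter on low values, rescaling to TPM or by median of ratios, a fit of each pair of groups alone, a term for the replicate number, a constant prior variance, no fold threshold, and each library left out in turn. After seeing the data, a correction of each library for GC content and transcript length (splines with 4 degrees of freedom each, over 12814 genes, 98.7% of those tested, taken from GENCODE transcripts) and a fit without both control replicate 1 and overexpression replicate 2 were added.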

Results

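RNA levels were measured in 9 KYSE-150 libraries: 3 control, 3 PAK5-overexpressing and 3 PAK5-silenced. Between 30414 and 31913 genes had an FPKM above 0 in a library, and between 12774 and 13279 had an FPKM of at least 1. Depth is unknown for these values. Pearson correlations of log2(FPKM + 1) across genes ran from 0.965 to 0.984 between control libraries, 0.959 to 0.986 between overexpressing libraries and 0.983 to 0.991 between silenced libraries. Between libraries of different groups they ran from 0.939 to 0.981, which overlaps the ranges within groups. Overexpression replicate 2 had a mean correlation of 0.9599 within its group and 0.967 with the other groups. For control replicate 3 the means were 0.9737 and 0.9744. Mitochondrially encoded mRNAs took 4.90% ± 1.98 of the FPKM sum in control libraries, 4.36% ± 1.12 in overexpressing libraries and 3.14% ± 0.367 in silenced libraries (SD, n = 3 each), and control replicate 1 stood at 7.14%. Libraries of 1 group also differed in a trend with the GC content of the genes, strongest in control replicate 1 and overexpression replicate 1.

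**Figure D1:**
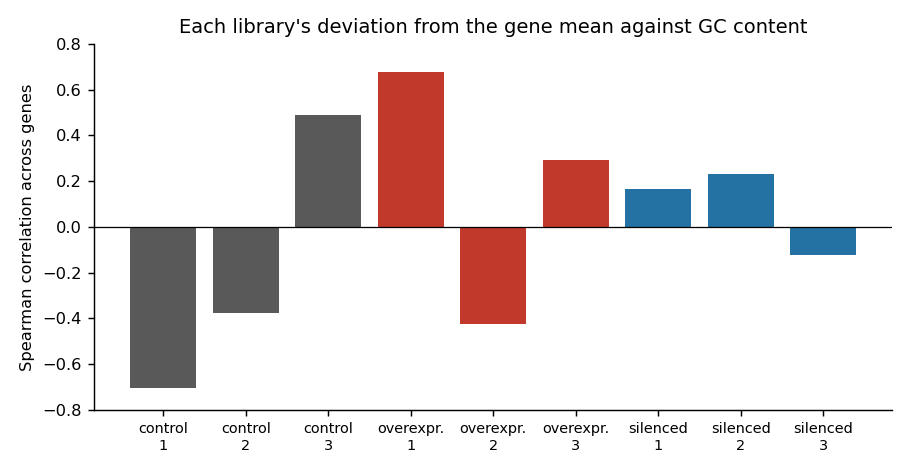
Spearman correlation across 12814 genes (bars, y axis starting from 0 in both directions) between each library's deviation from the gene mean on the log2(FPKM + 1) scale and the GC content of the gene's transcripts. Control libraries ran from -0.703 to 0.49 and overexpressing libraries from -0.423 to 0.678, and silenced libraries stayed between -0.125 and 0.232.

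PAK5 (ENSG00000101349, chromosome 20, 9537389 to 9839041 on GRCh38) was examined first as the gene the study targeted. The overexpressing libraries held 90.8, 109 and 91.4 FPKM of PAK5, a mean of 97.2 ± 10.5 (SD, n = 3). In the controls PAK5 stood at 0.0136, 0 and 0.261 FPKM, and in all 3 silenced libraries it was listed at 0. Overexpression exceeded control by 6.49 on the log2(FPKM + 1) scale (SE 0.14, adjusted p = 1.62e-10 by limma), with an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow. Silenced and control libraries differed by -0.12 (SE 0.14, adjusted p = 0.668), with an exact permutation p of 0.4. The controls were already near 0, so a fall of PAK5 mRNA in the silenced libraries was not detectable in this table.

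**Figure D2:**
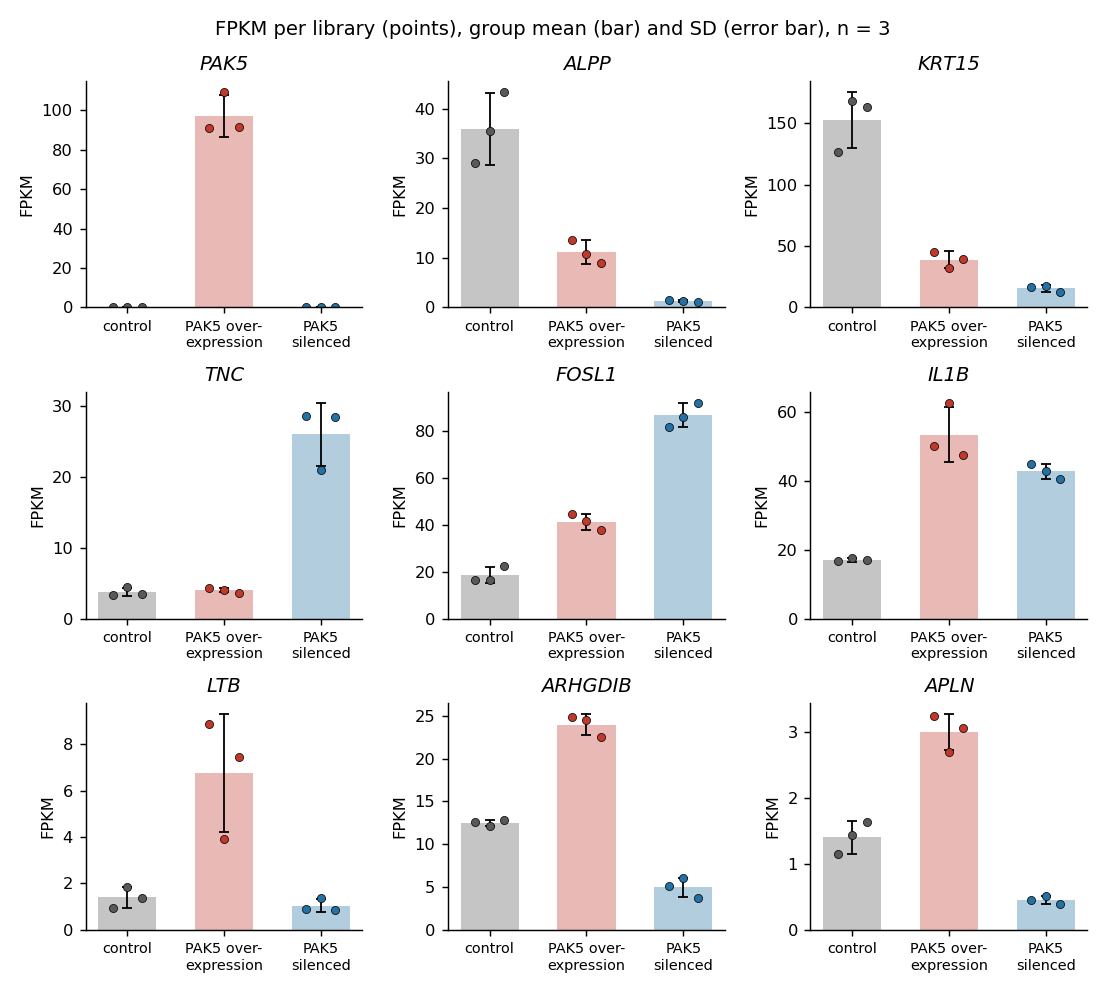
FPKM (linear y axis, starting at 0) of 9 genes in each library, with points for the 3 libraries of a group, bars for the group mean and error bars for the SD. PAK5 reached a mean of 97.2 FPKM in the overexpressing libraries only, ALPP and KRT15 were below control in both modified groups, and ARHGDIB and APLN lay above control in the overexpressing libraries and below it in the silenced ones.

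The comparison of silenced with control cells, the one for which the series design states thresholds, asked which genes differed in the libraries labelled as PAK5-silenced. No fall of PAK5 mRNA was detectable there and no scrambled control is named. These differences are therefore not shown to follow from a loss of PAK5, and effects of the silencing reagent were not tested. The gene for placental alkaline phosphatase, ALPP (ENSG00000163283, chromosome 2, 232378534 to 232382889), fell from 36.0 ± 7.21 to 1.33 ± 0.135 FPKM, a log2 fold change of -3.97 (SE 0.18, adjusted p = 7.45e-07). KRT15 (ENSG00000171346, chromosome 17, 41513743 to 41522529), a keratin of basal squamous cells, fell from 153 ± 22.9 to 15.5 ± 2.58 FPKM, a log2 fold change of -3.23 (SE 0.18, adjusted p = 3.09e-06). The extracellular matrix gene TNC (ENSG00000041982, chromosome 9, 115019578 to 115118257) rose from 3.76 ± 0.627 to 26.0 ± 4.43 FPKM, a log2 fold change of 2.50 (SE 0.16, adjusted p = 8.88e-06). FOSL1 (ENSG00000175592, chromosome 11, 65892049 to 65900573), which encodes a subunit of the transcription factor AP-1, rose from 18.5 ± 3.37 to 86.5 ± 5.12 FPKM, a log2 fold change of 2.18 (SE 0.15, adjusted p = 1.26e-05). All values are means ± SD of 3 libraries.

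In all, 170 of 12980 genes were called in the silenced libraries, 87 higher and 83 lower, and 920 had an adjusted p under 0.05, 475 higher and 445 lower. After TNC, the highest rises among the 144 protein-coding calls were those of the oxidoreductase gene DHRS2 (log2 fold change 2.45), the parathyroid hormone-like hormone gene PTHLH (2.21), FOSL1, the epidermal growth factor receptor ligand AREG (2.13), the cytokine IL11 (1.97), the uridine phosphorylase UPP1 (1.91) and the adaptor LAT2 (1.89). Beyond ALPP and KRT15, the deepest falls were in the intracellular chloride channel gene CLIC3 (-2.50), the epithelial transcription factor ELF3 (-2.33), METTL7A (-2.09), the guanine nucleotide exchange factor FGD3 (-1.93), LRG1 (-1.82) and IGFL1 (-1.77). Adjusted p-values of these 16 genes ran from 7.45e-07 for ALPP to 0.000136 for UPP1. All 16 stayed called with any 1 library left out. Of 70 list members that rose or fell and were named by the list part of the rule alone, 34 kept an adjusted p under 0.05 in each such fit and the highest value was 0.226. At a pseudocount of 0.1 in place of 1 the number of called genes was 296.

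Genes induced by ERK signalling formed the list with the most members higher in the silenced libraries. Of 20 tested members of the ERK pathway output list, 12 rose and 0 fell (13 and 0 adjusted over the list alone), led by FOSL1, AREG, the growth factor gene HBEGF (1.28) and MYC (1.39), with an adjusted p of 5.11e-12. Its adjusted p = 0.254 with an estimated correlation. In the integrated stress and unfolded protein response list, 7 of 26 members rose and 0 fell, as they did when adjusted over the list alone (adjusted p = 1.49e-05; adjusted p = 0.482 with an estimated correlation). They included the stress-induced SESN2 (1.54), the endoplasmic reticulum chaperone HSPA5 (1.16), XBP1 (0.76) and STC2 (0.68). Among Wnt/beta-catenin targets, MYC, the adhesion receptor CD44 (0.94) and the ubiquitin ligase RNF43 (0.56) rose, 3 of 8 members with 0 falling (4 and 0 adjusted over the list alone). The Wnt list had an adjusted p of 0.00587 and an adjusted p = 0.532 with an estimated correlation. MYC also stands in the ERK list. NF-kB targets and cytokines went both ways. IL1B (1.27), IL1A (1.60), CXCL2 (0.94), TRAF1 (0.81) and IL6 (0.69) rose, while ICAM1 (-0.81) and TNFAIP2 (-0.71) fell, IL6, ICAM1 and TNFAIP2 being named after their values were seen. These were 5 and 2 of 17 members (8 and 5 adjusted over the list alone). As a whole the list had an adjusted p of 0.0420 for a rise and an adjusted p = 0.639 with an estimated correlation. The NF-kB call was lost without control replicate 1 (adjusted p = 0.0723), without silenced replicate 3 (0.0536), without both control replicate 1 and overexpression replicate 2 (0.0994) and with the GC and length correction (0.115). It was also lost at a mean FPKM of at least 5 (0.346), after rescaling to TPM (0.0552) and in the fit of 2 groups (0.0521).

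Lists that were lower in the silenced libraries held sterol, antigen-processing, proliferation and immediate early genes. Of 22 tested cholesterol biosynthesis genes, 4 fell and 0 rose (9 and 0 adjusted over the list alone), TM7SF2 (-0.97), the lanosterol synthase LSS (-0.82), HMGCS1 (-0.78) and FDPS (-0.65). After correction for GC and length 17 of them fell, and that correction moved 72 of the member counts of the lists by more than 1.5 times and left 18 within it. The sterol list had an adjusted p of 2.37e-05 and an adjusted p = 0.482 with an estimated correlation. The tapasin gene TAPBP (-0.91) and the immunoproteasome subunits PSMB10 (-1.08) and PSMB9 (-0.90) fell, 3 of 13 antigen presentation genes both over all genes and adjusted over the list alone. This list had an adjusted p of 0.00996 and an adjusted p = 0.639 with an estimated correlation. Immediate early genes FOSB (-0.75), NR4A1 (-0.70) and FOS (-0.61) fell, 3 of 13 by either adjustment, with an adjusted p of 0.0396 and an adjusted p = 0.490 with an estimated correlation. In the G2/M and mitosis list 1 of 25 genes fell by either adjustment, KIF20A (-0.60), with an adjusted p of 0.0396 and an adjusted p = 0.774 with an estimated correlation. The 13 mitochondrially encoded mRNAs had a median log2 fold change of -0.62, with 0 passing limma's test over all genes or adjusted over the list alone and 6 at an unadjusted p under 0.05. As a list they had an adjusted p of 0.00167 and an adjusted p = 0.639 with an estimated correlation. Their share of the FPKM sum was 3.14% in the silenced and 4.90% in the control libraries. Without control replicate 1 the mitochondrial and the G2/M calls were lost (adjusted p = 0.0723 for both), and without control replicate 3 the antigen presentation (0.112) and immediate early calls (0.145). The immediate early call was also lost at a mean FPKM of at least 5 (0.0869) and in the fit of 2 groups (0.0521), and the mitochondrial call without both control replicate 1 and overexpression replicate 2 (0.0855).

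The other lists were not called in the silenced libraries, although single members passed the test. Interferon response genes RSAD2 (1.23), OASL (1.02) and IFIT1 (0.93) rose and BST2 (-1.09) fell, in a list with 7 of 18 members higher and 1 lower (7 and 2 adjusted over the list alone, list adjusted p = 0.0830). Among mesenchymal genes 5 of 12 rose and 0 fell (5 and 2 adjusted over the list alone, list adjusted p = 0.0513), among them CD44, AXL (0.75), SNAI2 (0.72) and ITGA5 (0.58, named after its value was seen). One epithelial junction gene of 22 fell by either adjustment, the E-cadherin gene CDH1 (-0.70), with a list adjusted p of 0.209. In the squamous basal list 3 of 18 rose and 2 fell (4 and 6 adjusted over the list alone, list adjusted p = 0.739), KRT15 and FGFR3 (-1.21) downward and, among those upward, the laminin gene LAMB3 (1.14) and the collagen COL17A1 (0.54, named after its value was seen). That list had a median of 0.23 and a mean of -0.14. Squamous differentiation genes had 1 of 8 higher, KLF4 (0.92), and 1 lower, NOTCH3 (-0.72), with 2 and 3 adjusted over the list alone and a list adjusted p of 0.607. SERPINE2 (1.15), MMP2 (0.70) and PLAUR (0.52, named after its value was seen) rose and the inhibitor TIMP2 (-0.88) fell among matrix proteases and inhibitors, where 4 of 16 were higher and 1 lower (5 and 1 adjusted over the list alone, list adjusted p = 0.254). In the TGF-beta list 2 of 17 rose, among them PMEPA1 (1.07), and 3 fell, CCN2, ID1 (-0.82) and TGFB2 (-0.86), with 2 and 4 adjusted over the list alone and a list adjusted p of 0.850.

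Further lists without a call had few members past the test. For G1/S and DNA replication 4 of 25 genes fell by either adjustment, among them TYMS (-0.63), CCNE2 (-0.79) and PCNA (-0.68), with a list adjusted p of 0.0513. With the GC and length correction 11 of its members fell and the list was called (adjusted p = 0.0111, and adjusted p = 0.121 with an estimated correlation). The p53 list had 4 of 22 higher, SESN2, AEN (0.93), PLK3 (0.72) and GADD45A (0.60), and 1 lower, CCNG1 (-0.86, named after its value was seen), with 5 and 1 adjusted over the list alone, a list adjusted p of 0.462, a median of -0.04 and a mean of 0.06. Of 21 apoptosis regulators 1 rose, BCL2L1 (0.57), and 2 fell, among them BCL2L11 (-0.75), 3 and 5 adjusted over the list alone, with a list adjusted p of 0.545. Hypoxia and glycolysis genes split evenly, VEGFA (0.94) and NDRG1 (0.75) rising and ADM (-1.05) and ALDOC (-0.72) falling among 23, with 3 and 2 adjusted over the list alone and a list adjusted p of 0.254. Of 18 YAP/TEAD targets AXL and DLC1 (0.64) rose and CCN2 and TGFB2 fell, with 2 and 4 adjusted over the list alone, and a list adjusted p of 0.0816. After correction for GC and length 2 rose and 7 fell and the YAP/TEAD list was called lower (adjusted p = 0.0367, and adjusted p = 0.494 with an estimated correlation). NRF2 targets SRXN1 (0.83), FTH1 (0.68) and FTL (0.64) rose and PRDX1 (-0.86) fell among 19, with 4 and 1 adjusted over the list alone, a list adjusted p of 0.484, a median of -0.08 and a mean of 0.07. Histone genes H3C10 (-0.63) and H4C9 (-0.66) fell and H2BC11 (0.49) rose among 16 by either adjustment, with a list adjusted p of 0.0513. In the PAK family (5 tested, list adjusted p = 0.925), oxidative phosphorylation (27, 0.518) and cytoplasmic ribosomal protein (26, 0.380) lists 0 genes passed limma's test by either adjustment, against 1, 4 and 3 at an unadjusted p under 0.05.

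Markers of other cell types were mostly too low to test. The leukocyte list had 2 of 15 genes tested, CD68 at 0.51 (adjusted p = 0.119) and LCP1 at -0.06, and the endothelial list 1 of 10, EGFL7 at 0.50 (adjusted p = 0.233), so neither list was tested. Adjusted over the list alone, CD68 was the 1 gene to pass among the leukocyte genes. Fibroblast markers had 3 of 13 tested and 1 lower by either adjustment, PDPN (-1.03), with a list adjusted p of 0.265. Of the 3 neuronal genes tested, MAP2 (0.34), TUBB3 (0.32) and SYT1 (0.01), 0 passed limma's test by either adjustment and 1 had an unadjusted p under 0.05 (list adjusted p = 0.283). The glandular list had 4 of 12 tested, of which MUC1 (-0.98) fell and KRT7 (0.73) passed only when adjusted over the list alone (list adjusted p = 0.305). KRT18 and KRT8, also made by this line, had the highest levels of any of these markers, means of 942 and 814 FPKM over the 9 libraries.

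The PAK5-overexpressing libraries were compared with the same controls. Besides PAK5 itself, the cyclin-dependent kinase gene CDK15 rose from 0.846 ± 0.271 to 5.01 ± 1.47 FPKM, a log2 fold change of 1.69 (SE 0.19, adjusted p = 0.00306). IL1B (ENSG00000125538, chromosome 2, 112829751 to 112836903), an inflammatory cytokine, rose from 17.1 ± 0.534 to 53.4 ± 8.05 FPKM, a log2 fold change of 1.58 (SE 0.14, adjusted p = 0.000721). The lymphotoxin beta gene LTB (ENSG00000227507, chromosome 6, 31580525 to 31582522) rose from 1.39 ± 0.443 to 6.76 ± 2.55 FPKM, a log2 fold change of 1.65 (SE 0.24, adjusted p = 0.0102). KRT15 fell to 39.0 ± 6.71 FPKM, a log2 fold change of -1.95 (SE 0.18, adjusted p = 0.000866), and ALPP fell to 11.2 ± 2.33 FPKM, a log2 fold change of -1.60 (SE 0.18, adjusted p = 0.00306).

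Fewer genes were called than after silencing: 32 genes, 22 higher and 10 lower, and 74 with an adjusted p under 0.05, 55 higher and 19 lower. Protein-coding calls numbered 24, with rises also in the protease inhibitor SERPINB7 (1.43), the hair keratin KRT81 (1.42), the cytokine IL32 (1.36), the metalloreductase STEAP1 (1.34) and FOSL1 (1.13). The 6 protein-coding falls were KRT15, ALPP, the AP-1 subunit FOSB (-1.15), the zinc finger gene ZSCAN31 (-1.12), ELF3 (-1.06) and the troponin gene TNNI2 (-1.05). The count was 20 without control replicate 2, and LTB, IL32, KRT81, ELF3 and ZSCAN31 missed the adjusted threshold without overexpression replicate 3 (adjusted p = 0.0681, 0.0575, 0.0681, 0.0681 and 0.0803). Without control replicate 2 the same held for FOSL1 (0.0526), KRT81 (0.0526), ELF3 (0.0653) and ZSCAN31 (0.0666), and ZSCAN31 also missed it without control replicates 1 (0.0684) or 3 (0.0515). ELF3 (-0.96) and TNNI2 missed the fold threshold without control replicate 3, as did TNNI2 without control replicate 2 or overexpression replicate 3 (-0.99). Of the 17 list members that rose or fell and were named by the list part of the rule alone, 1, ECM1, kept an adjusted p under 0.05 in each fit that left out 1 library, the highest value being 0.197. The count of called genes was 52 at a pseudocount of 0.1, 15 with no filter on low values and 19 at a mean FPKM of at least 5. The share of calls that were higher, 68.8% of the 32, ran from 53.8% of 39 genes after rescaling to TPM to 72.4% of 29 without control replicate 3. With the GC and length correction it was 54.8% of 31 genes. That correction also left 346 genes past the test in both comparisons with 1 direction, so more than 74 genes then passed with overexpression.

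NF-kB targets and cytokines led the lists in the overexpressing libraries. Of 17 members 5 rose and 0 fell (13 and 0 adjusted over the list alone), IL1B, IL1A (1.08), TRAF1 (0.76), IL6 (0.78) and IL23A (0.80, named after its value was seen). The list had an adjusted p of 5.73e-12 and an adjusted p = 0.172 with an estimated correlation. The interferon response genes RSAD2 (0.86) and IFI6 (1.05) rose, 2 of 18 with 0 falling (9 and 0 adjusted over the list alone), with an adjusted p of 7.08e-07 and an adjusted p = 0.172 with an estimated correlation. The IFI6 call was kept in 1 of 6 fits that left out 1 library and under 1 of 10 other alternatives. In the ERK output list FOSL1, AREG (1.08), ETV4 (0.86), ETV5 (0.71) and SPRED3 (0.67) rose and EGR1 (-0.73) fell among 20 (9 and 1 adjusted over the list alone), ETV5 and SPRED3 being named after their values were seen. The ERK list's adjusted p was 1.16e-05 and an adjusted p = 0.221 with an estimated correlation. Matrix protease list members such as PLAUR (0.97) and SERPINE2 (0.87) rose, 3 of 16 with 0 falling (5 and 0 adjusted over the list alone). For the protease list the adjusted p was 0.00200 and an adjusted p = 0.522 with an estimated correlation. Of 12 mesenchymal genes 2 rose, CD44 (0.80) among them, with 0 falling (5 and 1 adjusted over the list alone), with an adjusted p of 0.00993 and an adjusted p = 0.221 with an estimated correlation. CD44 was also the 1 of 8 Wnt targets that rose (2 and 0 adjusted over the list alone), with an adjusted p of 0.0357 and an adjusted p = 0.609 with an estimated correlation. Among 13 immediate early genes FOSB, FOS (-0.91) and EGR1 fell and 0 rose (5 lower and 0 higher adjusted over the list alone). The immediate early list had an adjusted p of 7.57e-05 and an adjusted p = 0.172 with an estimated correlation. With the GC and length correction the NF-kB list also passed with an estimated correlation (adjusted p = 0.0423), while the mesenchymal (adjusted p = 0.0782) and Wnt (0.0769) calls were lost, the Wnt call also without control replicate 2 (0.0946), control replicate 3 (0.0717) or overexpression replicate 2 (0.135), or without both control replicate 1 and overexpression replicate 2 (0.0731).

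Several lists were called in the overexpressing libraries without a member past the test over all genes. G1/S and DNA replication genes had a median of 0.27, with E2F1 at 0.57 (adjusted p = 0.158), an adjusted p of 9.94e-05 and an adjusted p = 0.522 with an estimated correlation, and 3 of 25 were higher when adjusted over the list alone and 7 at an unadjusted p under 0.05. With the GC and length correction 5 of them rose over all genes and the list passed with an estimated correlation too (adjusted p = 0.0357). Oxidative phosphorylation genes, with NDUFB8 at 0.57 (adjusted p = 0.215), had a median of 0.25 over 27 genes, 0 past limma's test adjusted over the list alone and 3 at an unadjusted p under 0.05, an adjusted p of 0.000722 and an adjusted p = 0.522 with an estimated correlation. Hypoxia and glycolysis genes had a median of 0.30 over 23 genes, 1 higher adjusted over the list alone and 10 at an unadjusted p under 0.05, an adjusted p of 0.00360 and an adjusted p = 0.609 with an estimated correlation. The hypoxia call was lost without both control replicate 1 and overexpression replicate 2 (0.0731). Cytoplasmic ribosomal protein genes had a median of 0.20 over 26 genes, 0 past limma's test adjusted over the list alone and 2 at an unadjusted p under 0.05, an adjusted p of 0.0141 and an adjusted p = 0.737 with an estimated correlation, and were not called with the GC and length correction (0.156) or without control replicate 3 (0.0970), overexpression replicate 1 (0.212) or overexpression replicate 3 (0.179). Epithelial junction genes, with DSC3 at -0.94 (adjusted p = 0.103) and DSP at -0.64 (adjusted p = 0.131), had a median of -0.28 over 22 genes, 2 lower adjusted over the list alone and 6 at an unadjusted p under 0.05, an adjusted p of 0.0239 and an adjusted p = 0.708 with an estimated correlation. That call was lost without control replicate 2 (0.0782), control replicate 3 (0.0717) or overexpression replicate 3 (0.0684). Replication-dependent histone genes had a median of -0.33 over 16 genes, 0 past limma's test adjusted over the list alone and 6 at an unadjusted p under 0.05, an adjusted p of 0.00360 and an adjusted p = 0.172 with an estimated correlation, and were not called without overexpression replicate 2 (0.305), without it and control replicate 1 (0.312) or at a mean FPKM of at least 5 (0.233).

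The remaining lists were not called after overexpression. PAK5 was the 1 of 5 tested PAK genes that rose, by either adjustment (list adjusted p = 0.0932). BCL2L1 (0.73) rose among 21 apoptosis regulators (1 and 1 adjusted over the list alone, list adjusted p = 0.847). KRT15 and FGFR3 (-0.89) fell among 18 squamous basal genes (0 higher and 3 lower adjusted over the list alone, list adjusted p = 0.155), ECM1 (1.03) rose among 8 squamous differentiation genes (2 and 2 adjusted over the list alone, list adjusted p = 0.920) and 1 gene rose among 17 TGF-beta targets (1 and 1 adjusted over the list alone, list adjusted p = 0.856). No gene passed limma's test over all genes in the G2/M (list adjusted p = 0.116), p53 (0.629), antigen presentation (0.232), integrated stress (0.232), cholesterol (0.259), YAP/TEAD (0.594), NRF2 (0.324) or mitochondrial mRNA (0.856) lists, nor among fibroblast (0.765), neuronal (0.425) or glandular markers (0.232). In that order 3, 2, 0, 4, 3, 5, 5, 0, 1, 1 and 2 members had an unadjusted p under 0.05. With the GC and length correction 3 G2/M genes rose and that list was called (adjusted p = 6.18e-05, and adjusted p = 0.374 with an estimated correlation). Adjusted over the list alone, 1 gene was higher in each of the YAP/TEAD, NRF2 and neuronal lists, 1 lower in the fibroblast list, and 2 higher in the untested leukocyte list, CD68 at 0.82 (adjusted p = 0.0874) and LCP1 at 0.36. Squamous differentiation genes had a mean of 0.02 and a median below 0, and the fibroblast list a median of 0.15 and a mean of -0.03. EGFL7, the single endothelial gene tested, stood at 0.38 (adjusted p = 0.468).

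**Figure D3:**
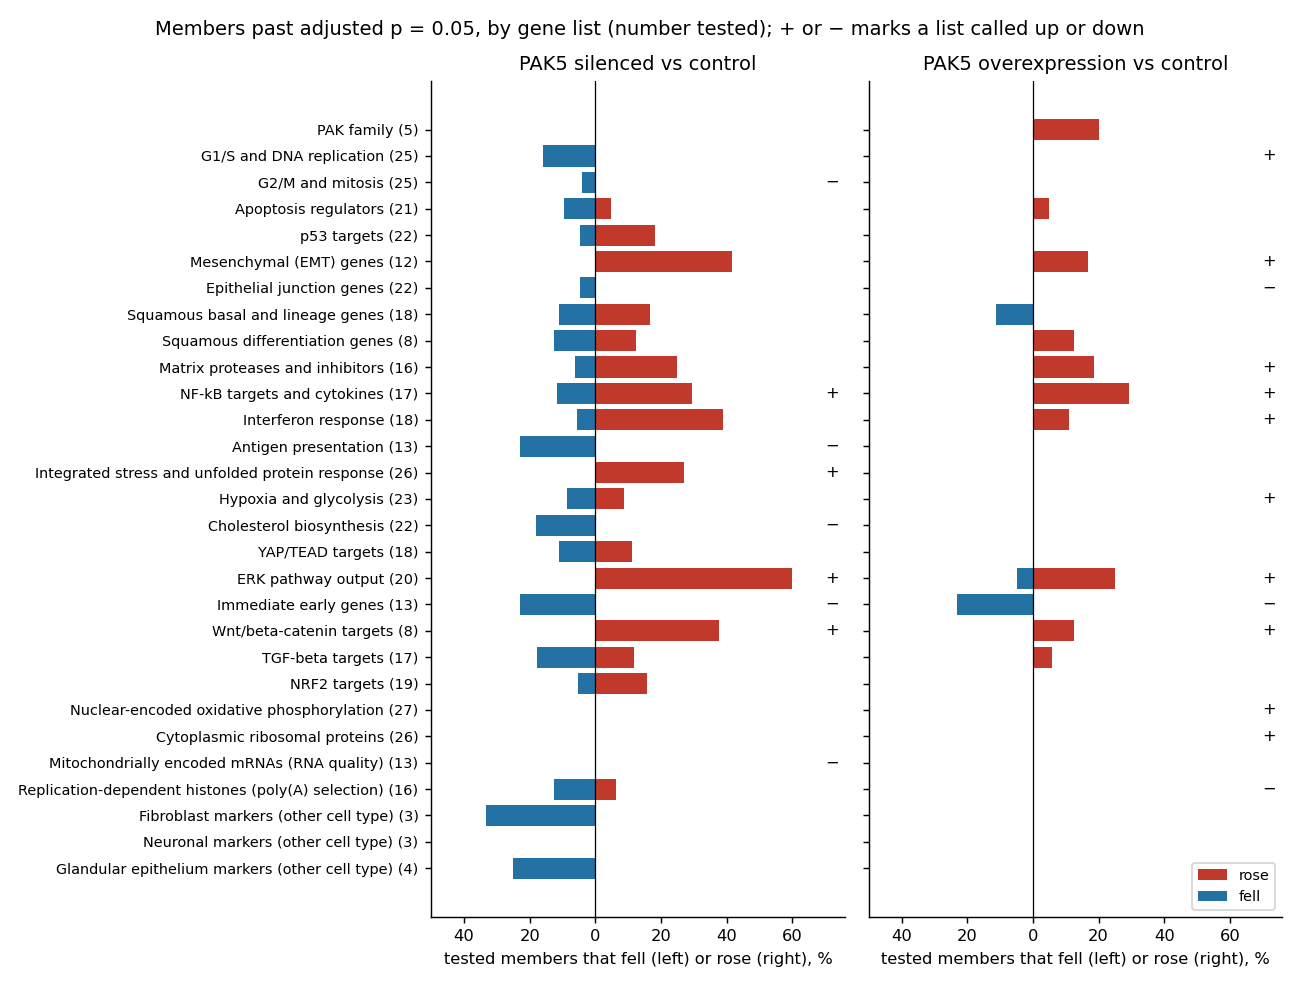
Percent of the tested members of each reported gene list with at least 3 tested members that rose (red, right) or fell (blue, left) at an adjusted p under 0.05, with the number tested in brackets and a plus or minus sign where the list was called at the preset correlation. ERK pathway output had 12 of 20 members higher in the silenced libraries, and NF-kB targets 5 of 17 higher in the overexpressing libraries.

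**Figure D4:**
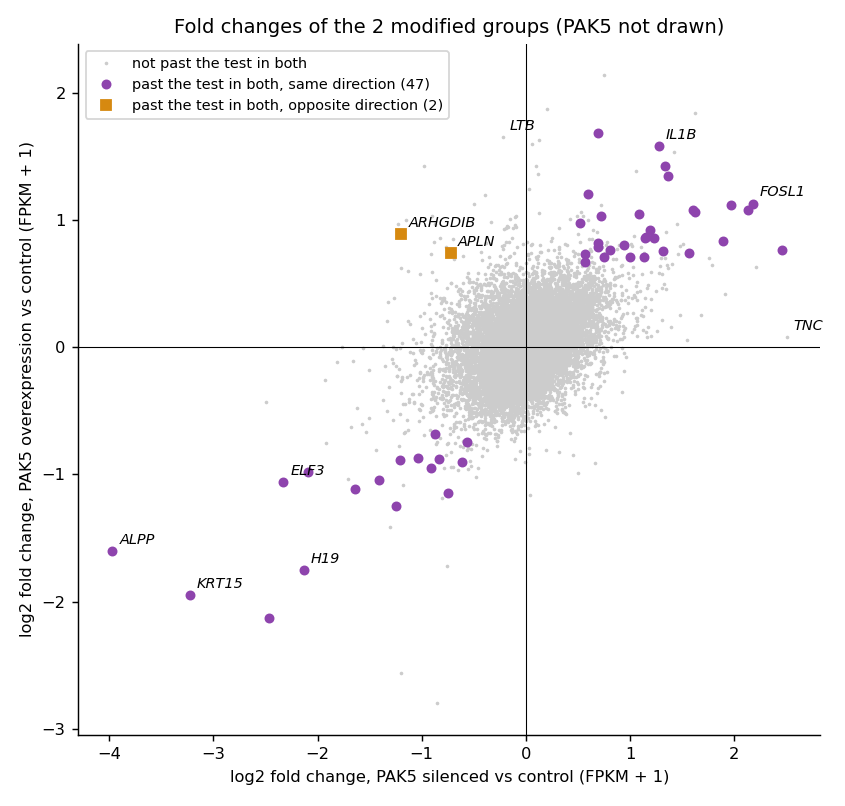
Log2 fold change on FPKM + 1 of each tested gene in PAK5-silenced (x axis) and PAK5-overexpressing libraries (y axis) against the same 3 controls, PAK5 itself left out. Purple circles are the 47 genes past the test in both comparisons with 1 direction, orange squares the 2 with opposite directions, ARHGDIB and APLN, and grey dots all others.

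A gene that followed PAK5 in both directions would move oppositely in the 2 modified groups, and 2 genes did, or 44 with the GC and length correction. PAK5 mRNA itself had no measurable fall in the silenced libraries (-0.12, adjusted p = 0.668 by limma). Opposite moves therefore do not show that a gene followed PAK5 mRNA. ARHGDIB (ENSG00000111348, chromosome 12, 14942017 to 14961728) had 12.5 ± 0.331 FPKM in control, 24 ± 1.24 in overexpressing and 4.96 ± 1.14 in silenced libraries, log2 fold changes of 0.89 (adjusted p = 0.0274) and -1.20 (adjusted p = 0.000916). The peptide hormone gene APLN (ENSG00000171388, chromosome X, 129645259 to 129654937) had 1.40 ± 0.249, 3 ± 0.273 and 0.452 ± 0.0598 FPKM, log2 fold changes of 0.74 (adjusted p = 0.0288) and -0.72 (adjusted p = 0.00746). Far more genes moved 1 way in both groups: 47, of which 30 rose and 17 fell, or 346 with that correction. Those that rose included STEAP1 (1.36 silenced, 1.34 overexpressing), SERPINB7 (1.33 and 1.43), IL1B, FOSL1 and IL11 (1.97 and 1.12). Those that fell included KRT15, ALPP and 3 noncoding genes, H19 (-2.13 and -1.75), NR4A1AS (-1.25 and -1.25) and RF01973 (-2.47 and -2.13). With no filter on low values these 3 genes missed the adjusted threshold in the overexpressing libraries (adjusted p = 0.0907, 0.0518 and 0.108), as did SERPINB7 (0.0619), and IL11 missed it with a replicate block (0.0588). NR4A1AS is uncertain because it lies antisense to another gene. RF01973, annotated as a miscellaneous RNA, spans only 52666 to 52734 on the scaffold KI270721.1, and FPKM of so short a feature are uncertain.

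Independent lists of these sizes would share 2.01 genes higher in both, 0.651 lower in both and 2.58 opposite. Simulated unchanged groups that shared the 3 control libraries gave a mean of 12.7 genes in 1 direction (range 0 to 1119 over 100 simulations) and 0 opposite. The fold changes of the 2 comparisons had a covariance of 0.0419, against a simulated mean of 0.0200 (range -0.0414 to 0.0883), a difference of 0.0219, and a correlation across genes, which are not independent replicates, of 0.4, against a simulated mean of 0.428. Over all tested genes the simulated share with the same sign in both comparisons had a mean of 64.4% (range 18.5 to 92.1). With 3 control libraries they could not be split into separate sets of 2, so part of the excess may come from the shared controls. Of the 170 genes called in the silenced libraries, 158 (92.9%) had the same sign under overexpression, a share that the shared controls raise, 30 of them with an adjusted p under 0.05. One gene, ARHGDIB, had the opposite sign with an adjusted p under 0.05. ARHGDIB and APLN did not pass against control in the overexpressing libraries without control replicate 2 (adjusted p = 0.144 and 0.134), where their log2 fold changes were 0.87 and 0.75, and both kept that call in 1 of 6 fits that left out 1 library. The number of opposite genes was 0 without any 1 of control replicates 1, 2 and 3, overexpression replicates 1 and 3 and silenced replicate 1, 1 without silenced replicate 2 or 3, and 4 without overexpression replicate 2. Without control replicates 1, 2 or 3 the number of genes moving 1 way in both groups was 22, 14 and 26, without overexpression replicates 1, 2 or 3 it was 28, 68 and 15, and without silenced replicates 1, 2 or 3 it was 22, 26 and 31.

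The overexpressing and silenced libraries were also compared directly, by a difference that leaves out the control means. The control libraries still entered the estimate of the spread in the fit of all 9 libraries. ALPP (2.37), ARHGDIB (2.08), CLIC3 (2.07), LTB (1.88) and the acute-phase gene SAA2 (1.85) were the highest protein-coding genes besides PAK5 (6.61) in the overexpressing over the silenced libraries. TNC (-2.42), DHRS2 (-1.70), PTHLH (-1.58), UPP1 (-1.49) and SESN2 (-1.48) were the lowest. TNC stood at 4 ± 0.297 FPKM in the overexpressing and 26.0 ± 4.43 in the silenced libraries (adjusted p = 2.92e-05). SAA2 is uncertain because reads of its near-identical copy may be shared. In total 124 genes were called, 97 higher and 27 lower with overexpression, or 78.2% higher, and 820 had an adjusted p under 0.05. After rescaling to TPM, the median of all genes stood at -0.15 and 197 genes were called with 45.7% higher. The share of higher calls therefore depends on the scaling. Without overexpression replicate 2 the count was 233.

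The list tests of this comparison, chosen after the data were seen, called 11 of 30 lists. Cholesterol biosynthesis genes were higher with overexpression, 9 of 22 rising (13 adjusted over the list alone), with an adjusted p of 6.94e-07 and an adjusted p = 0.519 with an estimated correlation. G1/S and DNA replication genes rose in 7 of 25 cases (11 adjusted over the list alone), with an adjusted p of 6.94e-07 and an adjusted p = 0.605 with an estimated correlation. ERK output genes were lower with overexpression than with silencing, 6 of 20 falling (8 adjusted over the list alone), with an adjusted p of 1.22e-06 and an adjusted p = 0.519 with an estimated correlation. Integrated stress genes fell in 5 of 26 cases (6 adjusted over the list alone), with an adjusted p of 0.00104 and an adjusted p = 0.701 with an estimated correlation. The other 7 calls, all higher with overexpression, were antigen presentation (adjusted p = 0.000252), G2/M (0.000215), oxidative phosphorylation (0.000522), mitochondrial mRNAs (0.00112), ribosomal proteins (0.00326), NF-kB targets (0.00661) and glandular markers (0.0465). None of the 11 passed camera with an estimated correlation, where 2 lists had an unadjusted p under 0.05. With the GC and length correction the G1/S list did pass (adjusted p = 0.0159). The ribosomal (0.0813) and glandular (0.182) calls were lost with the GC and length correction, without overexpression replicate 1 (0.0996 and 0.170) and without silenced replicate 3 (0.0746 and 0.0687). The glandular call was also lost with no filter on low values (0.113), at a mean FPKM of at least 5 (0.266), after median-of-ratios rescaling (0.0643), in the fit of 2 groups (0.0615) and with a replicate block (0.0551).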

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

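The tests of the GC content and transcript length trends, of the correction for them and of opposite effects of like size were chosen after the results they bear on were seen, while the simulations of shared controls and the other splits of the libraries were set beforehand.

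ARHGDIB and APLN stand out because their changes against control had opposite signs in the overexpressing and the silenced libraries, each past limma's test. The direct difference between the modified groups is made of those same changes in the same fit, so it adds no separate support. That difference was 2.08 (adjusted p = 6.66e-05 by limma) for ARHGDIB and 1.46 (adjusted p = 0.000202) for APLN on the log2(FPKM + 1) scale. The 3 overexpressing libraries lay above the 3 silenced ones in both genes, which the opposite changes also favour. The rise against control kept its size with any 1 library left out, from 0.86 to 0.93 for ARHGDIB and from 0.66 to 0.81 for APLN, but its adjusted p passed in 1 of 6 such fits. Over the alternatives that lost it, the adjusted p ran from 0.0654 to 0.144 for ARHGDIB and from 0.0513 to 0.141 for APLN. Groups of 3 libraries were not tested for single libraries far from the others.

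The changes of both modified groups against control went mostly 1 way, 47 genes against 2, where simulated unchanged groups gave at most 1119 and 0. After the GC and length correction the counts were 346 against 44, where simulated unchanged groups gave at most 2 and 0. Neither group changed in these simulations, so they do not show what 1 changed group beside an unchanged one would give. Correlations of the fold changes as high as the observed ones came up in 59 of 100 simulated sets before the correction and 73 of 100 after it. A trend with GC content and transcript length is argued against as the whole cause, because all 47 genes kept their direction after correction. Of these, 44 still passed the test in both comparisons, but passing was easier then, since 346 genes did so. The covariance went from 0.0419 to 0.0324 with the correction, so a partial contribution of such a trend stays open. Chance values of the 3 shared control libraries stay open: 14 of 100 simulated sets of unchanged groups had a covariance as high as the observed 0.0419, and 15 of 100 after the correction, although 2 of 100 had as many same-direction genes before it and 0 after it. Opposite effects of like size stay open for genes that differ between the modified groups, because the test run cannot decide them. Of 123 such genes, called between those groups and without PAK5, 79 had the control mean between the other means. That share of 64.2% lies between the bounds set for and against. The count uses signs and not sizes, and a gene changed in 1 group alone can fall on either side. No share for unchanged genes was computed, so no conclusion is drawn from it. A response common to handling or modifying the cells may also contribute and was not tested, since no vector or scrambled control is named.

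Libraries of 1 group differed along a leading axis that held 49.3% of the variance within groups. The gene weights of that axis had a Spearman correlation of 0.765 with GC content across genes, which fits a technical GC trend as a possible source of that spread. The correlation with transcript length was -0.338, between the bounds set for and against it, so a length trend cannot be told apart from its absence in that axis. No biological explanation was tested, because the labels give no difference between replicates.

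Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05, and in each the real split alone, 1 of 10, had as many called genes. Every other split mixes libraries of both groups, so a difference between the groups widens its spread and can lower its count whatever the cause. The silenced against control split called 170 genes and the highest other split 0 by limma. The overexpression against silenced split called 124 and the highest other 1. The overexpression against control split called 32 and the highest other 24. That other split set control replicates 1 and 2 and overexpression replicate 2 against the rest and had 2695 genes at an adjusted p under 0.05, against 74 for the real one, which points to a structure of the samples. The same 3 libraries had negative correlations with GC content, -0.703, -0.377 and -0.423.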

How the results depend on the processing

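The GC and length correction and the fit without both control replicate 1 and overexpression replicate 2 were chosen after seeing the data, and the other alternatives beforehand.

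The change of PAK5 kept its sign and its side of the threshold under each alternative, with leave-one-out ranges of 6.41 to 6.60 against control and 6.52 to 6.66 against the silenced libraries for overexpression, and -0.18 to -0.01 for silencing, which never passed. No named gene or called list reversed under any alternative.

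The counts of called genes for silenced against control, overexpression against control and overexpression against silenced libraries were 170, 32 and 124. Without a fold threshold they were 920, 74 and 820 by construction. A pseudocount of 0.1 gave 296, 52 and 256, which held 169, 31 and 122 of the genes called at 1, and 1 opposite gene. With no filter on low values overexpression gave 15 called genes, 13 of them shared, with 0 opposite genes and 23 moving the same way in both groups, and 15 lists were called in the silenced libraries. More genes were then tested. At a mean FPKM of at least 5, where 12 of the 32 genes were not tested, overexpression gave 19 called genes, with 1 opposite gene and 25 moving the same way. Rescaled to TPM, the median of all genes stood at -0.10 for overexpression against control and -0.15 for overexpression against silenced. That rescaling divides by the FPKM column sums, 426577 to 446376 in overexpressing, 382312 to 415494 in control and 360975 to 415060 in silenced libraries. The higher sums with overexpression lower its values by construction. Overexpression against silenced then gave 197 genes with 45.7% higher, beside 78.2%, so that share depends on the scaling. There was 1 opposite gene, and other causes were not tested. A fit of the 2 groups only gave 0 opposite genes and 18 moving the same way, with fewer libraries behind each variance.

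With a replicate block, overexpression gave 18 called genes, 0 opposite genes and 13 moving the same way. Deviations from the group means gave no sign that the numbers pair the libraries, with correlations above 0.1 in 1 of 9 same-numbered pairs. The check cannot exclude pairing. It was run before the GC correction, and the axis related to GC content held 49.3% of the variance within groups. The GC and length correction gave 44 opposite genes and 346 moving the same way, while the counts of called genes were 167, 31 and 124, of which 142, 24 and 97 were shared. It took FOSL1 (1.13 to 0.92), IL11 (1.12 to 0.90), ECM1 (1.03 to 0.90) and IFI6 (1.05 to 0.88) under overexpression, and PMEPA1 and OASL under silencing (1.02 to 0.95 for OASL), below the fold threshold. Without control replicate 1 and overexpression replicate 2 the overexpression against silenced count was 245, with 1 opposite gene and 26 moving the same way, and the cause was not tested. Median-of-ratios rescaling and a constant prior variance kept each of 10 counts within 1.5 times.

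Leave-one-out fits gave 150 to 222 called genes for silencing, 20 to 42 for overexpression and 93 to 233 between the modified groups, 0 to 4 opposite genes and 14 to 68 moving the same way. Lists called ran from 7 to 12 for silencing and 10 to 16 for overexpression. Of named-gene tests, 270 of the leave-one-out fits lost the call, as did 181 under other alternatives, and the cause was not tested. Depth is unknown, so what it limits cannot be given.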

Other observations

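The genes in this part were chosen after their values were seen, and no hypothesis was tested on them.

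TALAM1, an antisense transcript of MALAT1, had 35.2 ± 18.5 FPKM in control, 4.81 ± 2.04 in overexpressing and 13.6 ± 2.68 in silenced libraries (SD, n = 3). The fall with overexpression was -2.56 (adjusted p = 0.00630 by limma), and the difference with silencing, -1.20, missed the threshold (adjusted p = 0.0530), with 3 of 3 libraries below the controls in each group. MALAT1 itself stood at 144.5, 154.0 and 143.6 FPKM and passed in neither comparison (adjusted p = 0.766 and 0.872). The strand setting is not stated, so the split of reads between the 2 genes is uncertain.

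All 22 mitochondrial tRNA genes were tested. Their median log2 fold change was -0.94 in silenced and 0.37 in overexpressing libraries against control, and 1.46 between the overexpressing and silenced libraries. By limma 2 were called lower in the silenced libraries and 8 higher in the overexpressing than in the silenced ones.

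Markers of other cell types had low medians, with a median over genes of the mean FPKM of 0.0887 for the leukocyte list, 0.0391 for fibroblast, 0.0592 for endothelial and 0.0892 for glandular markers. The most abundant were LCP1 (72.3 FPKM) and CD68 (54.3) among leukocyte, FBLN1 (12.4) among fibroblast, EGFL7 (7.30) among endothelial TUBB3 (14.8) among neuronal and KRT18 (942) and KRT8 (814) among glandular markers. Of the fibroblast markers 2 stand in another list.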
